A study of Arabidopsis thaliana with 24 samples.

How the data were processed

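RNA was measured in whole 4-day-old Arabidopsis thaliana seedlings of the Col-0 background. The 24 libraries form 8 groups of 3 replicates: wild type (WT) and the agb1 mutant, each given 0.2% DMSO or 40 µM N-linolenoylethanolamine (NAE 18:3, an N-acylethanolamine) for 1 h or 3 h. AGB1 encodes the beta subunit of the heterotrimeric G protein, and the labels do not name the agb1 allele. Seedlings grew in liquid Murashige and Skoog medium with 1% sucrose at 21 °C and were treated in 20 mL, per the labels' protocols. The libraries were poly(A)-selected with a stranded kit and sequenced as paired reads of 75 bp. Replicates are numbered in the labels, but nothing there says whether they are separate cultures. The p-values therefore measure the spread between these samples.

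The raw tables, 1 per time point, hold counts per gene locus that the authors made from reads aligned with STAR to TAIR10, per the submitters' processing notes. Neither the counting tool nor its strand setting is stated. The other tables hold a normalized signal that, per the submitters' processing notes, involved DESeq2. In each of the 24 libraries every normalized value, multiplied by that library's median-of-ratios size factor, equalled the raw count within 0.01. These tables served only as a check of the columns. Each table has 32833 loci, of which 32548 matched the RefSeq annotation of TAIR10.1. The other 285 are organelle loci, 133 plastid and 152 mitochondrial. Because the builds differ, gene names, products and strand neighbours were taken from that annotation. Of all loci, 8812 overlap another on the opposite strand. Without a stated strand setting, reads of such neighbours cannot be told apart, and reads of near-identical paralogs could have been split in either way.

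All comparisons started from the raw counts. Loci passed edgeR's filterByExpr by group (minimum count 10, minimum total 15), which left 21255 loci at 1 h, 20672 at 3 h and 21700 for all 24 libraries. Library sizes were scaled by TMM. The robust quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3 was fitted to the 12 libraries of each time point. It tested the effect of NAE 18:3 in WT, the effect in agb1, the difference between these effects, and agb1 against WT under DMSO. A fit of all 24 libraries tested how the NAE effect differed between 3 h and 1 h. Genes were called at a Benjamini-Hochberg adjusted p under 0.05. Values are log2 fold changes with standard errors (SE), and levels are TMM-scaled CPM values with the SD of 3 libraries. "Rose" and "fell" are used for called genes.

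The comparisons, tests, alternatives, naming rule and 23 gene lists were fixed before the data were examined. The lists cover photosynthesis and plastid functions, stress, hormone, defence, lipid, G-protein, growth, clock, sugar and pigment genes, and markers of root and of seed storage. All 465 list entries were found in the files. Further lists held the 2656 loci whose annotated product has a chloroplast or thylakoid location, and the plastid-encoded and mitochondrion-encoded loci. Camera (limma 3.58.1) compared each list with all other tested genes at a preset inter-gene correlation of 0.01. Its p-values were adjusted over all 208 pairs of list and comparison, and the tests were repeated with an estimated correlation. With the preset correlation 95 of the 208 passed, and with the estimated one 13. Where a list's adjusted p missed 0.05 with the estimated correlation, that p is given beside it. Fry, a rotation test, asked whether genes that responded in WT at one time point responded differently in agb1 at the other.

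In each within-time comparison the naming rule took the 5 largest rises and 5 largest falls among called genes with a mean of at least 5 CPM. The 3 and 3 libraries of such a comparison between a pair of groups also had to be without overlap, which chance gives for 10% of genes. From each list with at least 3 called members it took the 2 with the smallest p. AGB1, GPA1, AGG1, AGG2, AGG3 and RGS1 were always taken, and for the time differences the 3 largest rises and falls. Genes named outside this rule are said to have been chosen after their values were seen.

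Depth ran from 18.0 to 61.9 M counts per library. The median SE of a log2 fold change was 0.107 for the NAE effect in WT at 1 h and 0.167 at 3 h. The scripts were tested on simulated data with known fold changes. For the genotype difference of the NAE effect, edgeR recovered 70.1% of the 67 genes changed 2-fold at 1 h and 41.8% at 3 h. For the NAE effect in WT it recovered 80.6% at 1 h and 71.6% at 3 h. In simulation it recovered 85.1% of 2-fold changes for agb1 against WT under DMSO at 1 h and 70.1% at 3 h. Each of these simulations changed 66 or 67 genes at 1.5-fold, 2-fold and 4-fold, among 21255 genes at 1 h and 20672 at 3 h. The data had a far larger share of called genes for NAE 18:3 in WT, 20.5% at 1 h and 58.5% at 3 h, so recovery there can differ.

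The alternatives were RLE scaling, no low-count filter, a mean of at least 10 CPM, removal of organelle loci, the replicate number as a block, DESeq2 1.42.0, a fit of only the 6 libraries compared, a 2-fold minimum, and leaving out each library in turn. Thinning all libraries to the smallest total of their time point was added after seeing the data. So were the comparison of agb1 with WT under NAE 18:3 and, under DMSO at 1 h, the removal of a trend on exon length and GC content. Other splits of the same libraries were refitted for every comparison and difference. Figures were drawn with matplotlib 3.10.9, and tables were prepared with pandas 2.3.3.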

Results

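Transcript levels were measured in 24 libraries of 4-day-old Arabidopsis seedlings, 3 for each combination of genotype (WT or agb1), treatment (DMSO or NAE 18:3) and time (1 h or 3 h). NAE 18:3 is a polyunsaturated N-acylethanolamine, a fatty acid amide that seedlings can break down by hydrolysis or oxidation. The question set by the study's title is whether the chloroplast-related transcript response to this lipid needs an intact heterotrimeric G protein, which agb1 seedlings lack if the mutant makes no beta subunit. Total counts were 18.0 to 61.9 M per library at 1 h (median 35.9 M) and 20.0 to 51.9 M at 3 h (median 30.9 M). At 3 h the groups differed in depth: the 6 WT libraries held 20.0 to 25.8 M counts, the agb1 libraries under DMSO 41.1 to 51.9 M and those under NAE 18:3 36.0 to 40.0 M. Replicate 2 of WT under DMSO at 1 h stood apart, with 18.0 M counts, 5.288% of them from ribosomal RNA, 1.177% plastid and 1.741% mitochondrial. The agb1 libraries under DMSO at 3 h were uneven. Between pairs of them the chi-square per degree of freedom against counting noise was 66.4, 47.4 and 83.9. In the other groups at 3 h it was at most 28.2. This measure grows with depth, which was also highest in that group at 3 h.

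AGB1 (AT4G34460) transcript was present in every agb1 library. At 1 h its level was 53.6 ± 2.67 CPM (SD, n = 3) in WT under DMSO and 47.9 ± 4.9 in agb1, a difference of -0.16 (SE 0.09) with an edgeR adjusted p of 0.245. Under NAE 18:3 at 1 h it was 62 ± 1.93 CPM in WT and 48.3 ± 6.03 in agb1. At 3 h it was 47.8 ± 0.536 CPM in WT under DMSO and 26 ± 4.52 in agb1, a difference of -0.88 (SE 0.12, adjusted p = 0.000231). NAE 18:3 raised it in WT at 3 h to 103 ± 9.04 CPM and in agb1 to 33.3 ± 1.84 CPM. The call of the rise in agb1 was lost in 4 alternatives, among them the fit of only the 6 libraries compared. The level at 1 h thus gives no check of the genotype labels, since a mutant can still make transcript. GPA1 (AT2G26300), the alpha subunit gene, rose by 1.52 (SE 0.12) in WT and by 0.66 in agb1 at 3 h. The difference between these effects was -0.85 for GPA1 (SE 0.16, adjusted p = 0.0158) and -0.75 for AGB1 (SE 0.17, adjusted p = 0.0289). The GPA1 difference missed the threshold without WT DMSO replicate 2, agb1 NAE replicate 1 or agb1 NAE replicate 2, and the AGB1 difference missed it in 8 alternatives.

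**Figure D1:**
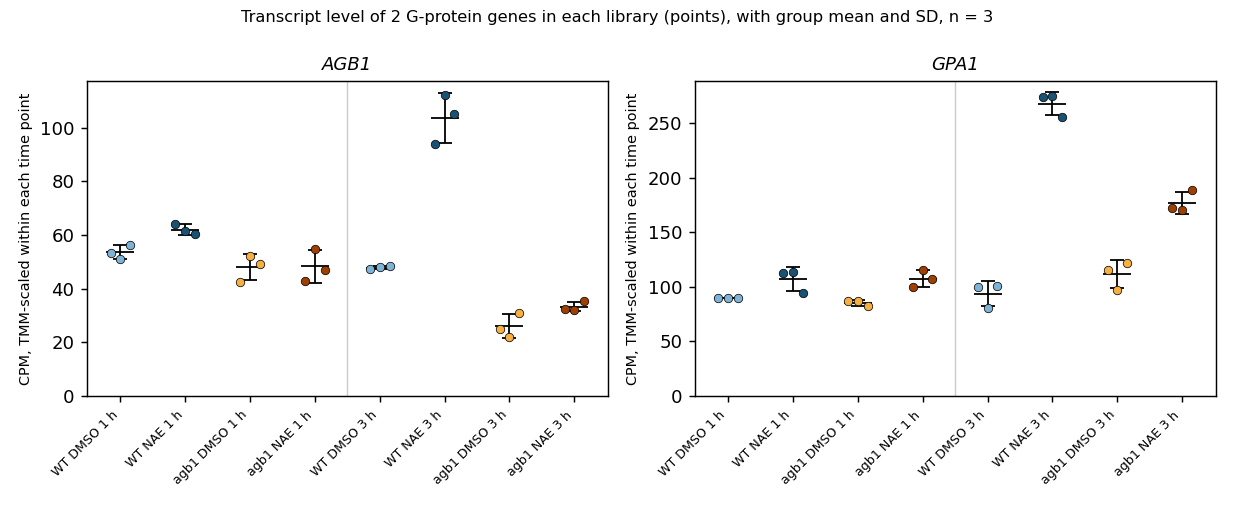
Level of AGB1 and GPA1 in CPM, scaled by TMM within each time point, for each of the 24 libraries (points), with group means and SD (bars, n = 3). At 3 h AGB1 lies at 103 CPM in WT under NAE 18:3 and at 33.3 CPM in agb1 under NAE 18:3.

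After 1 h of NAE 18:3, WT seedlings had higher transcript levels of defence and oxidative stress genes. The largest rises were in AT2G47950 (4.49, SE 0.21), the carbonic anhydrase gene AT2G28210 (4.23, SE 0.22), the ubiquitin ligase gene CNI1 (AT5G27420, 4.1, SE 0.14), the transcription factor gene MYB41 (AT4G28110, 4.06, SE 0.31) and the subtilase gene SBT3.3 (AT1G32960, 4.04, SE 0.20). CNI1 went from 8.08 ± 0.917 to 141 ± 4.11 CPM (SD, n = 3). The largest falls were in BGLU35 (AT1G51470, -3.28, SE 0.42), the F-box gene AT2G36090 (-3.23, SE 0.19), the oxygenase gene AT3G61400 (-3.22, SE 0.14), CYP702A5 (AT4G15393, -2.74, SE 0.19) and AT2G28780 (-2.39, SE 0.18). In all, 2644 genes rose and 1704 fell of 21255 tested, and 684 and 286 of these changed at least 2-fold. Without WT NAE replicate 2 the count of 4348 called genes was 2684, with 917 falls.

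Of 26 measured defence genes 17 rose with NAE 18:3 in WT at 1 h (21 adjusted over the list alone), with a median of 0.66 and a camera adjusted p of 1.49e-21. The transcription factor genes WRKY22 (AT4G01250) and ERF5 (AT5G47230) rose by 1.78 (SE 0.08) and 2.24 (SE 0.12). In the oxidative stress list 7 of 18 rose and 2 fell (8 and 2 adjusted over the list alone, adjusted p = 2.93e-09), among them the zinc finger gene ZAT12 (AT5G59820, 2.68, SE 0.11) and the kinase gene OXI1 (AT3G25250, 1.61, SE 0.08). In the heat shock list 13 of 22 rose (14 higher and 2 lower adjusted over the list alone), with a median of 0.73 and an adjusted p of 1.9e-11 (adjusted p = 0.217 with an estimated correlation). The factor genes HSFA7A (AT3G51910) and HSFB2A (AT5G62020) rose by 1.82 (SE 0.12) and 1.57 (SE 0.11). Of 30 detoxification genes 16 rose and 2 fell (20 and 2 adjusted over the list alone), with a median of 0.66 and an adjusted p of 3.99e-08 (adjusted p = 0.518 with an estimated correlation). GSTU3 (AT2G29470) rose by 4.04 (SE 0.38) from 0.148 to 2.59 CPM, and UGT73B5 (AT2G15480) by 1.42 (SE 0.13).

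Hormone genes moved at 1 h in WT too. Of 27 jasmonate genes 9 rose and 1 fell (10 and 1 adjusted over the list alone, adjusted p = 0.000407, and adjusted p = 0.518 with an estimated correlation), including LOX4 (AT1G72520, 1.65, SE 0.16) and the repressor gene JAZ1 (AT1G19180, 1.1, SE 0.11). Of 18 auxin genes 7 rose (7 adjusted over the list alone, adjusted p = 0.000127, and adjusted p = 0.263 with an estimated correlation), including IAA2 (AT3G23030, 1.06, SE 0.07) and GH3.2 (AT4G37390, 2.13, SE 0.17). In the abscisic acid list 4 of 20 rose (4 higher and 1 lower adjusted over the list alone, adjusted p = 0.0836), among them NCED3 (AT3G14440, 2.03, SE 0.16), a key enzyme of abscisic acid synthesis, and ABF3 (AT4G34000, 0.78, SE 0.11). In the touch and cold list 3 of 8 rose (5 adjusted over the list alone, adjusted p = 6e-08, and adjusted p = 0.0552 with an estimated correlation), among them DREB2A (AT5G05410, 2.86, SE 0.13) and CML38 (AT1G76650, 1.67, SE 0.11). Of 15 clock genes 9 rose (9 adjusted over the list alone, adjusted p = 2.72e-06, and adjusted p = 0.349 with an estimated correlation), with RVE1 (AT5G17300) at 1.86 (SE 0.17) and BOA (AT5G59570) at 1.21 (SE 0.07). Of 12 endoplasmic reticulum stress genes 6 rose (9 adjusted over the list alone, adjusted p = 0.00231, and adjusted p = 0.416 with an estimated correlation), including BZIP60 (AT1G42990, 0.64, SE 0.09) and TIN1 (AT5G64510, 1.05, SE 0.17). Of 18 flavonoid genes 1 rose and 7 fell (1 and 10 adjusted over the list alone, adjusted p = 0.000261, and adjusted p = 0.32 with an estimated correlation), including the flavonol synthase gene FLS1 (AT5G08640, -0.83, SE 0.09) and the chalcone isomerase gene TT5 (AT3G55120, -0.84, SE 0.11).

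Photosynthesis lists did not pass in WT at 1 h with all libraries. The antenna list had a median of -0.14 (adjusted p = 0.177), and 2 of 30 photosystem genes fell, with a median of -0.11 (adjusted p = 0.0623). Both passed as lower without WT DMSO replicate 2 and without WT NAE replicate 3, and the photosystem list also with the replicate number as a block. The WT libraries at 1 h differed between treatments in a trend with exon length. Across genes, the Spearman correlation of a library's deviation from its time point's mean with exon length was -0.39, -0.21 and -0.07 under DMSO. Under NAE 18:3 it was -0.15, 0.19 and 0.19, and the weight of this trend in the NAE effect was not tested. In the greening list 6 of 24 rose (median 0.03, adjusted p = 0.494), among them HY5 (AT5G11260, 0.83, SE 0.17), a light-signalling factor gene, and the plastid sigma factor gene SIG5 (AT5G24120, 1.49, SE 0.32). Medians were 0.02 for the Calvin cycle, 0.02 for chlorophyll biosynthesis and -0.05 for plastid ribosomal proteins. Of the 2459 tested loci with an annotated chloroplast or thylakoid location, 197 rose and 130 fell (adjusted p = 0.532). In the lipid metabolism list 2 of 18 rose and 1 fell, with PLDGAMMA1 (AT4G11850) at 0.84 (SE 0.10) and LOX1 (AT1G55020) at -0.65 (SE 0.14). Of 12 G-protein genes 4 rose and 1 fell (4 and 3 adjusted over the list alone, adjusted p = 0.694), among them XLG2 (AT4G34390, 0.62, SE 0.09) and NDL2 (AT5G11790, -0.62, SE 0.09), while AGG1 (AT3G63420), AGG2 (AT3G22942), AGG3 (AT5G20635) and RGS1 (AT3G26090) had values of 0.16, -0.28, -0.36 and 0.09 without passing. In the sugar starvation list 5 of 13 rose and 2 fell (adjusted p = 0.0569), with TPS11 (AT2G18700) at 1.51 (SE 0.14) and TPS8 (AT1G70290) at 1.46 (SE 0.16). That list missed the threshold with all libraries and passed in 6 alternatives. Of 19 root markers 4 rose (adjusted p = 0.337), among them the stem cell gene WOX5 (AT3G11260, 1.09, SE 0.15) and TIP2;3 (AT5G47450, 1.06, SE 0.21). The cell cycle list had a median of 0.03 (adjusted p = 0.872), and the 4 tested seed storage markers one of -0.02 (adjusted p = 0.975).

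In agb1 the 1 h response held many of the genes called in WT. AT2G47950 (5.54, SE 0.21), CNI1 (4.28, SE 0.15), MYB41 (4.16, SE 0.33), AT2G28210 (3.69, SE 0.21) and SBT3.3 (3.3, SE 0.19) were again the largest rises. The largest falls were in AT2G36090 (-3.23, SE 0.19), BGLU35 (-2.75, SE 0.40), CYP702A5 (-2.63, SE 0.18), the brassinosteroid-related gene BEE3 (AT1G73830, -2.49, SE 0.57) and AT3G61400 (-2.47, SE 0.13). In all, 1890 genes rose and 1045 fell in agb1, 595 and 230 of them at least 2-fold, and without agb1 DMSO replicate 2 the falls numbered 655. Of the genes that rose, 1481 were called in both genotypes, where independent lists would share 235, and 719 fell in both, where independent lists would share 84. The calls in both went in opposite directions for 2 of 2202 genes. Of the 684 genes that rose at least 2-fold in WT, 560 (81.9%) also rose in agb1, and of the 286 that fell at least 2-fold, 64% fell.

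List by list, agb1 at 1 h had 18 of 22 heat shock genes higher (18 adjusted over the list alone) with a median of 1.04 (adjusted p = 3.71e-24). HSFA7A rose by 2.01 (SE 0.11) and HSFB2A by 1.48 (SE 0.11). Of 26 defence genes 18 rose (median 0.72, adjusted p = 3.71e-24), with WRKY22 at 1.90 (SE 0.08) and ERF5 at 2.29 (SE 0.12). In the oxidative stress list 8 of 18 rose (9 adjusted over the list alone, adjusted p = 1.9e-11), ZAT12 by 2.43 (SE 0.11) and OXI1 by 1.52 (SE 0.08). Of 30 detoxification genes 13 rose and 2 fell (16 and 2 adjusted over the list alone, adjusted p = 2.84e-08, and adjusted p = 0.518 with an estimated correlation), with GSTU3 at 4.74 (SE 0.40) and GSTF8 (AT2G47730) at 0.70 (SE 0.08). Of 27 jasmonate genes 13 rose (15 adjusted over the list alone, adjusted p = 1.79e-08, and adjusted p = 0.32 with an estimated correlation). In the touch and cold list 4 of 8 rose (5 adjusted over the list alone, adjusted p = 1.97e-09), with DREB2A at 2.49 (SE 0.12). Auxin genes rose in 7 of 18 cases (adjusted p = 7.44e-05, and adjusted p = 0.263 with an estimated correlation), and abscisic acid genes in 4 of 20 (adjusted p = 0.00403, and adjusted p = 0.518 with an estimated correlation), NCED3 by 2.37 (SE 0.16) and NAC019 (AT1G52890) by 1.73 (SE 0.30). Of 15 clock genes 6 rose (adjusted p = 0.000668, and adjusted p = 0.518 with an estimated correlation) and of 12 endoplasmic reticulum stress genes 3 (adjusted p = 0.00403, and adjusted p = 0.431 with an estimated correlation). Of 18 flavonoid genes 9 fell (10 adjusted over the list alone, adjusted p = 8.86e-05, and adjusted p = 0.263 with an estimated correlation), FLS1 by -0.66 (SE 0.09). The root marker list passed only when WT NAE replicate 3, a library outside this comparison, was left out. Among its members WOX5 rose by 1.78 (SE 0.14) and the nitrate transporter gene NRT2.1 (AT1G08090) fell by 3.17 (SE 0.54), to 0.353 CPM. The photosystem and plastid ribosomal lists passed only when agb1 DMSO replicate 3 was left out.

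The NAE effect at 1 h differed between the genotypes for 16 genes, all of which rose in WT and had a lower value in agb1, where 5 rose, 1 fell and 10 were not called. The difference contains the WT value, so the subtraction itself favours this direction. The gene with the smallest p was AT3G03790, an ankyrin repeat and RCC1 family gene, which changed by 1.16 in WT and by -0.03 in agb1 (difference -1.19, SE 0.12, edgeR adjusted p = 0.00235). AT1G19200 (-1.63, SE 0.25), AT4G32480 (-1.56, SE 0.22), AT2G20670 (-1.25, SE 0.18) and the aspartyl protease gene AT5G19120 (-1.13, SE 0.17) each had an adjusted p of 0.0334. AT1G19200 rose by 0.73 in WT and fell by 0.90 in agb1, while AT2G20670 rose in both, by 3.07 and 1.82. Among the other 11, chosen after their values were seen, were the carbohydrate kinase gene AT3G59480 (-1.37, SE 0.23), the kinase gene CIPK12 (AT4G18700, -0.65, SE 0.10), the beta-amylase gene BMY3 (AT5G18670, -1.08, SE 0.17), the phosphate sensor gene SPX2 (AT2G26660, -0.73, SE 0.12) and DGD1 (AT3G11670, -0.75, SE 0.12), which makes the galactolipid of plastid membranes. At an unadjusted p under 0.05 there were 1937 genes, and DESeq2 called 78, 15 with a higher and 63 with a lower value in agb1. The count of 16 was 3, 4 and 1 without WT DMSO replicates 1, 2 and 3, and 32 (4 higher and 28 lower), 1 and 3 without WT NAE replicates 1, 2 and 3. It was 1, 2 and 4 without agb1 DMSO replicates 1, 2 and 3, and 2, 5 and 1 without agb1 NAE replicates 1, 2 and 3.

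Some lists shifted between genotypes at 1 h by small amounts. The photosystem list had a median difference of 0.23 (adjusted p = 1.17e-09, and adjusted p = 0.518 with an estimated correlation) and the antenna list one of 0.23 (adjusted p = 0.000683, and adjusted p = 0.724 with an estimated correlation). Plastid ribosomal genes had a median difference of 0.15 (adjusted p = 4.24e-05, and adjusted p = 0.706 with an estimated correlation) and heat shock genes one of 0.23 (adjusted p = 0.00054, and adjusted p = 0.518 with an estimated correlation). Jasmonate genes differed by 0.26 (adjusted p = 0.0323, and adjusted p = 0.782 with an estimated correlation), clock genes by -0.23 (adjusted p = 0.00384, and adjusted p = 0.568 with an estimated correlation) and lipid metabolism genes by -0.09 (adjusted p = 0.0243, and adjusted p = 0.622 with an estimated correlation). The DMSO libraries that enter these differences also differed between the genotypes in a trend with exon length, and between them the photosystem and plastid ribosomal lists shifted by -0.19 and -0.27. The jasmonate call was lost without WT DMSO replicate 3, WT NAE replicate 2, agb1 DMSO replicate 2 or 3, or agb1 NAE replicate 3. The lipid call was lost without WT DMSO replicate 1 or 2, WT NAE replicate 3, agb1 DMSO replicate 2 or agb1 NAE replicate 3. The antenna call was lost without WT DMSO replicate 3 or WT NAE replicate 1. Without WT DMSO replicate 1 the clock and plastid ribosomal calls were lost, the clock call also without WT NAE replicate 3. AGB1, GPA1, AGG1, AGG2, AGG3 and RGS1 had differences of -0.20, 0.08, 0.11, 0.02, 0.13 and -0.17 at 1 h, with adjusted p from 0.599 to 0.985.

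Under DMSO at 1 h, the photosystem and plastid ribosomal protein lists passed as lower in agb1 with the preset correlation only, and the WT and agb1 libraries also differed in a trend with transcript length. Across genes, the Spearman correlation of a library's deviation from the mean of its time point with exon length was -0.39, -0.21 and -0.07 in the WT libraries and 0.29, 0.29 and -0.02 in the agb1 libraries. Of 30 photosystem genes 11 were lower (13 adjusted over the list alone, median -0.19, adjusted p = 2.26e-06, and adjusted p = 0.667 with an estimated correlation), among them PSBR (AT1G79040, -0.59, SE 0.11) and PSB28 (AT4G28660, -0.46, SE 0.10). Of 23 plastid ribosomal genes 9 were lower (22 adjusted over the list alone, median -0.27, adjusted p = 2.12e-09, and adjusted p = 0.518 with an estimated correlation), with PSRP5 (AT3G56910) at -0.51 (SE 0.10) and PSRP6 (AT5G17870) at -0.50 (SE 0.12). Of 20 Calvin cycle genes 3 were lower (5 adjusted over the list alone, adjusted p = 0.000354, and adjusted p = 0.706 with an estimated correlation), with CP12-2 (AT3G62410) at -0.82 (SE 0.12). Of 19 antenna genes 2 were lower, with a list median of -0.01 (adjusted p = 0.612). Of 2459 loci with a chloroplast location 129 were higher and 271 lower (adjusted p = 0.0128, and adjusted p = 0.716 with an estimated correlation). Higher in agb1 were AT4G33720 (3.13, SE 0.32), CORI3 (AT4G23600, 2.58, SE 0.31), the triterpene synthase gene MRN1 (AT5G42600, 2.18, SE 0.36), the malate synthase gene MLS (AT5G03860, 2.01, SE 0.34) and AIR1 (AT4G12550, 1.89, SE 0.12). Lower were AT1G23110 (-1.90, SE 0.41), the peroxidase gene AT5G64120 (-1.90, SE 0.14), SERAT3;2 (AT4G35640, -1.85, SE 0.19), CYP71A12 (AT2G30750, -1.82, SE 0.17) and NHL10 (AT2G35980, -1.72, SE 0.32).

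Further members named by the rule in this comparison moved in both directions. FSD1 (AT4G25100), the iron superoxide dismutase gene, was lower by -1.70 (SE 0.26), and FER1 (AT5G01600) by -0.35 (SE 0.08). CHLM (AT4G25080) was lower by -0.36 (SE 0.08) and PORA (AT5G54190) higher by 1.03 (SE 0.27). GSTF3 (AT2G02930), GSTU8 (AT3G09270), JAZ9 (AT1G70700) and AOC1 (AT3G25760) were lower by -1.06, -0.76, -0.56 and -0.67. ABI1 (AT4G26080), ABF3, WRKY70 (AT3G56400), PLDGAMMA1 and PLDGAMMA3 (AT4G11840) were higher by 0.32, 0.46, 0.80, 0.47 and 0.35. In the endoplasmic reticulum stress list 3 of 12 were higher (6 adjusted over the list alone, adjusted p = 0.00157, and adjusted p = 0.398 with an estimated correlation), among them BIP3 (AT1G09080, 1.58) and BIP1 (AT5G28540, 0.45). In the clock list 2 of 15 were higher and 1 lower (adjusted p = 0.00323, and adjusted p = 0.557 with an estimated correlation), PRR9 (AT2G46790) by 1.38 and ELF4 (AT2G40080) by -0.38, and in the touch list 2 of 8 were higher (4 adjusted over the list alone, adjusted p = 0.00446, and adjusted p = 0.347 with an estimated correlation). BAM5 (AT4G15210) was lower by -1.63 and BZIP11 (AT4G34590) higher by 0.28. In all 1196 genes were higher and 1223 lower in agb1. The count of 2419 called genes was 926 without WT DMSO replicate 1, 851 without agb1 DMSO replicate 1 and 905 without agb1 DMSO replicate 2.

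After 3 h of NAE 18:3, WT seedlings had 12094 genes called, 6079 higher and 6015 lower of 20672 tested, with 2971 and 2823 changed at least 2-fold. The scaling centres the fold changes (median -0.003 over all genes). With 58.5% of genes called, the balance of rises and falls therefore depends on it. All 22 heat shock genes rose, with a median of 4.22 (adjusted p = 2.09e-52). The small heat shock protein genes HSP23.5 (AT5G51440) and HSP17.6B (AT2G29500) went from 42.4 ± 1.7 to 1420 ± 89.6 CPM and from 23.3 ± 1.48 to 1360 ± 172 CPM (SD, n = 3). The largest rises were in AT2G47950 (8.34, SE 0.29), the transporter gene ABCG40 (AT1G15520, 8.11, SE 0.48), AT2G23110 (7.57, SE 0.29), AT3G43250 (7.39, SE 0.41) and AT2G28210 (7.14, SE 0.31). ABCG40 went from 19 ± 5.38 to 5250 ± 1030 CPM. The largest falls were in the pectin lyase-like gene AT1G60590 (-7.85, SE 0.69), BGLU35 (-6.95, SE 0.87), BGLU34 (AT1G47600, -6.04, SE 0.72), the methyltransferase gene AT1G73600 (-5.68, SE 0.38) and the receptor kinase gene CRK30 (AT4G11460, -5.61, SE 0.43). BGLU34 and BGLU35 are near-identical copies, as are several heat shock, glutathione transferase and antenna genes, so their separate values are uncertain.

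Detoxification, jasmonate and defence lists rose in WT at 3 h. Of 30 detoxification genes 28 rose (28 adjusted over the list alone), with a median of 2.92 and an adjusted p of 5.34e-15 (adjusted p = 0.349 with an estimated correlation), GSTU3 by 5.88 (SE 0.31) and GSTU5 (AT2G29450) by 2.3 (SE 0.12). Of 27 jasmonate genes 20 rose and 2 fell (21 and 2 adjusted over the list alone, median 1.65, adjusted p = 3.78e-09, and adjusted p = 0.169 with an estimated correlation), with AOC1 at 2.95 (SE 0.14) and JAZ10 (AT5G13220) at 2.54 (SE 0.13). Of 28 defence genes 21 rose (median 1.52, adjusted p = 2.29e-09, and adjusted p = 0.147 with an estimated correlation), WRKY22 by 4.84 (SE 0.21) and WRKY33 (AT2G38470) by 2.88 (SE 0.14). In the oxidative stress list 11 of 18 rose and 3 fell (adjusted p = 0.000306, and adjusted p = 0.349 with an estimated correlation), with ZAT7 (AT3G46090) at 5.44 (SE 0.27) and OXI1 at 4.02 (SE 0.19). Auxin genes rose in 10 of 15 cases and fell in 3 (median 1.4, adjusted p = 0.00614, and adjusted p = 0.416 with an estimated correlation), GH3.3 (AT2G23170) by 5.09 (SE 0.22). In the touch list 5 of 8 rose (adjusted p = 0.00202, and adjusted p = 0.349 with an estimated correlation), CML38 by 4.43 (SE 0.26) and TCH3 (AT2G41100) by 2.31 (SE 0.18). Of 12 G-protein genes 8 rose and 3 fell (8 and 4 adjusted over the list alone, adjusted p = 0.00413, and adjusted p = 0.182 with an estimated correlation), NDL1 (AT5G56750) by 2.15 (SE 0.10). In the endoplasmic reticulum stress list 5 of 12 rose and 2 fell (adjusted p = 0.0328, and adjusted p = 0.712 with an estimated correlation), BZIP60 by 2.70 (SE 0.14) and TIN1 by 3.31 (SE 0.18). In the abscisic acid list 10 of 20 rose and 4 fell (adjusted p = 0.0511), the phosphatase genes ABI2 (AT5G57050) and HAI2 (AT1G07430) by 3.06 (SE 0.19) and 4.58 (SE 0.33). That list missed the threshold with all libraries and passed in 8 alternatives.

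The flavonoid list and, with the preset correlation only, several chloroplast lists and the cell cycle list passed as lower in WT at 3 h. The plastid ribosomal and plastid-encoded lists did not pass. Of 17 flavonoid genes 13 fell (13 adjusted over the list alone, median -1.56, adjusted p = 2.77e-07), FLS1 by -4.17 (SE 0.13) and the chalcone synthase gene CHS (AT5G13930) by -3.69 (SE 0.19), from 667 ± 110 to 51.7 ± 12.4 CPM (SD, n = 3). Of 24 greening genes 20 fell and 2 rose (median -0.66, adjusted p = 1.4e-05, and adjusted p = 0.416 with an estimated correlation), among them GLK1 (AT2G20570, -1.59, SE 0.10), a regulator of chloroplast genes, and MURE (AT1G63680, -1.46, SE 0.09). Of 19 antenna genes 10 fell (9 adjusted over the list alone, median -0.33, adjusted p = 0.00349, and adjusted p = 0.77 with an estimated correlation), LHCB2.1 (AT2G05100) from 282 ± 43.1 to 65.3 ± 2.91 CPM and LHCB2.2 (AT2G05070) from 289 ± 50.3 to 75.4 ± 2.54 CPM. Of 30 photosystem genes 16 fell (median -0.46, adjusted p = 0.0141, and adjusted p = 0.818 with an estimated correlation), PSB28 by -0.92 (SE 0.10) and PSAH2 (AT1G52230) by -0.79 (SE 0.09). The photosystem list call was lost without WT DMSO replicate 3. Calvin cycle genes fell in 14 of 20 cases (median -0.57, adjusted p = 0.00184, and adjusted p = 0.712 with an estimated correlation), FBA1 (AT2G21330) by -1.83 (SE 0.16) and PRK (AT1G32060) by -1.35 (SE 0.13). Of 23 chlorophyll genes 13 fell and 2 rose (adjusted p = 0.0196, and adjusted p = 0.768 with an estimated correlation), with PORC (AT1G03630) at -1.43 (SE 0.11) and the stress-inducible HEMA2 (AT1G09940) at 2.42 (SE 0.14). Of 24 cell cycle genes 17 fell and 1 rose (median -0.84, adjusted p = 0.00479, and adjusted p = 0.77 with an estimated correlation), among them MCM2 (AT1G44900, -1.48, SE 0.18) and CYCA1;1 (AT1G44110, -1.85, SE 0.26). Of 2441 loci with a chloroplast location 478 rose and 1044 fell (median -0.22, adjusted p = 0.00696, and adjusted p = 0.416 with an estimated correlation).

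The remaining lists in WT at 3 h did not pass. Of 23 plastid ribosomal genes 2 rose and 2 fell (adjusted p = 0.865), PRPL24 (AT5G54600) by 0.34 (SE 0.10) and PSRP2 (AT3G52150) by -0.51 (SE 0.10). In the lipid metabolism list 5 of 18 rose and 5 fell (adjusted p = 0.611), LOX1 by -2.16 (SE 0.15) and PLDGAMMA1 by 1.34 (SE 0.14). Clock genes rose in 9 of 15 cases and fell in 3 (adjusted p = 0.14), BOA by 2.11 (SE 0.17) and PRR7 (AT5G02810) by 0.80 (SE 0.10). In the sugar list 7 of 13 rose and 2 fell (adjusted p = 0.209), TPS11 by 3.27 (SE 0.39). Of 17 root markers 4 rose and 1 fell (adjusted p = 0.439), WOX5 by 4.3 (SE 0.30) and SCR (AT3G54220) by -1.05 (SE 0.12). Of 4 seed storage markers 1 fell (adjusted p = 0.729).

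In agb1 the 3 h response again held most genes called in WT. AT2G47950 (8.36, SE 0.28), the alternative oxidase gene AOX1D (AT1G32350, 7.75, SE 0.34), ABCG40 (7.66, SE 0.47), GSTU3 (7.50, SE 0.33) and AT3G43250 (6.72, SE 0.38) had the largest rises. BGLU34 (-8.44, SE 0.78), BGLU35 (-7.64, SE 0.77), the expansin gene EXPA11 (AT1G20190, -5.61, SE 0.38), AT2G22590 (-5.16, SE 0.28) and BEE3 (-5.12, SE 0.34) had the largest falls. In all 5073 genes rose and 5369 fell, 2265 and 2083 of them at least 2-fold. With 50.5% of genes called, this balance too depends on the scaling. Shared with WT were 4407 rises and 4350 falls, where independent lists would share 1492 and 1562. The calls in both went in opposite directions for 49 of 8806 genes. Of the genes that changed at least 2-fold in WT, 2594 of 2971 (87.3%) also rose and 2290 of 2823 (81.1%) also fell in agb1.

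All 22 heat shock genes rose in agb1 at 3 h as well (median 3.00, adjusted p = 1.76e-38), HSP23.5 by 3.37 (SE 0.10) and HSP17.6B by 3.56 (SE 0.13). Of 30 detoxification genes 28 rose (28 and 1 lower adjusted over the list alone, median 2.27, adjusted p = 7.8e-16, and adjusted p = 0.263 with an estimated correlation). Jasmonate genes rose in 23 of 27 cases and fell in 2 (median 1.61, adjusted p = 1.07e-14), JAZ10 by 2.55 (SE 0.13) and AOC1 by 2.65 (SE 0.14). Of 28 defence genes 22 rose and 1 fell (23 and 1 adjusted over the list alone, adjusted p = 1.64e-10, and adjusted p = 0.107 with an estimated correlation), with ERF5 at 2.78 (SE 0.14) and WRKY33 at 2.66 (SE 0.14). In the oxidative stress list 12 of 18 rose and 3 fell (adjusted p = 6.17e-06, and adjusted p = 0.179 with an estimated correlation), ZAT7 by 5.61 (SE 0.27). Of 12 G-protein genes 9 rose and 3 fell (adjusted p = 0.0134, and adjusted p = 0.263 with an estimated correlation), with NDL1 at 1.86 (SE 0.10) and XLG2 at 1.18 (SE 0.13). Auxin genes rose in 9 of 15 cases and fell in 3 (adjusted p = 0.0433, and adjusted p = 0.554 with an estimated correlation), GH3.3 by 4.40 (SE 0.21), clock genes rose in 9 of 15 and fell in 1 (adjusted p = 0.0263, and adjusted p = 0.598 with an estimated correlation), and touch genes rose in 6 of 8 (7 adjusted over the list alone, adjusted p = 8.86e-05, and adjusted p = 0.259 with an estimated correlation). In the endoplasmic reticulum stress list 4 of 12 rose and 5 fell (adjusted p = 0.568), and in the abscisic acid list 8 of 20 rose and 3 fell (adjusted p = 0.0803). BZIP28 (AT3G10800), BZIP60, HAI2, ABI2, DREB2A and CDF1 (AT5G62430) rose by 1.53, 1.68, 5.80, 2.23, 3.93 and 1.67. DOX1 (AT3G01420) fell by 2.68 (SE 0.27) and LOX1 by 1.52 (SE 0.15).

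Of the chloroplast lists in agb1 at 3 h, those of the Calvin cycle, greening and chloroplast location passed as lower, with the preset correlation only. Of 19 antenna genes 6 rose and 5 fell (median 0.03, adjusted p = 0.975), LHCB1.1 (AT1G29920) by 1.37 (SE 0.17) and LHCA6 (AT1G19150) by -1.64 (SE 0.15). Of 30 photosystem genes 1 rose and 9 fell (adjusted p = 0.309), ATPD (AT4G09650) by -0.71 (SE 0.11). Calvin cycle genes fell in 12 of 20 cases (13 adjusted over the list alone, median -0.39, adjusted p = 0.00567, and adjusted p = 0.768 with an estimated correlation), CP12-2 by -2.0 (SE 0.16) and RBCS1B (AT5G38430) by -1.48 (SE 0.16). Greening genes fell in 15 of 24 cases and rose in 2 (median -0.59, adjusted p = 0.000457, and adjusted p = 0.518 with an estimated correlation), GLK2 (AT5G44190) by -1.90 (SE 0.15) and SIG6 (AT2G36990) by -1.11 (SE 0.08). Of 23 chlorophyll genes 8 fell and 2 rose (adjusted p = 0.514), with HEMA2 at 2.06 (SE 0.14) and PORC at -0.70 (SE 0.11). Of 2441 loci with a chloroplast location 388 rose and 859 fell (adjusted p = 0.0295, and adjusted p = 0.518 with an estimated correlation). Flavonoid genes fell in 13 of 17 cases (median -1.28, adjusted p = 2.53e-08), FLS1 by -4.02 (SE 0.13) and TT5 by -3.54 (SE 0.19). Of 24 cell cycle genes 4 fell (adjusted p = 0.247), MCM2 by -0.82 (SE 0.17).

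**Figure D2:**
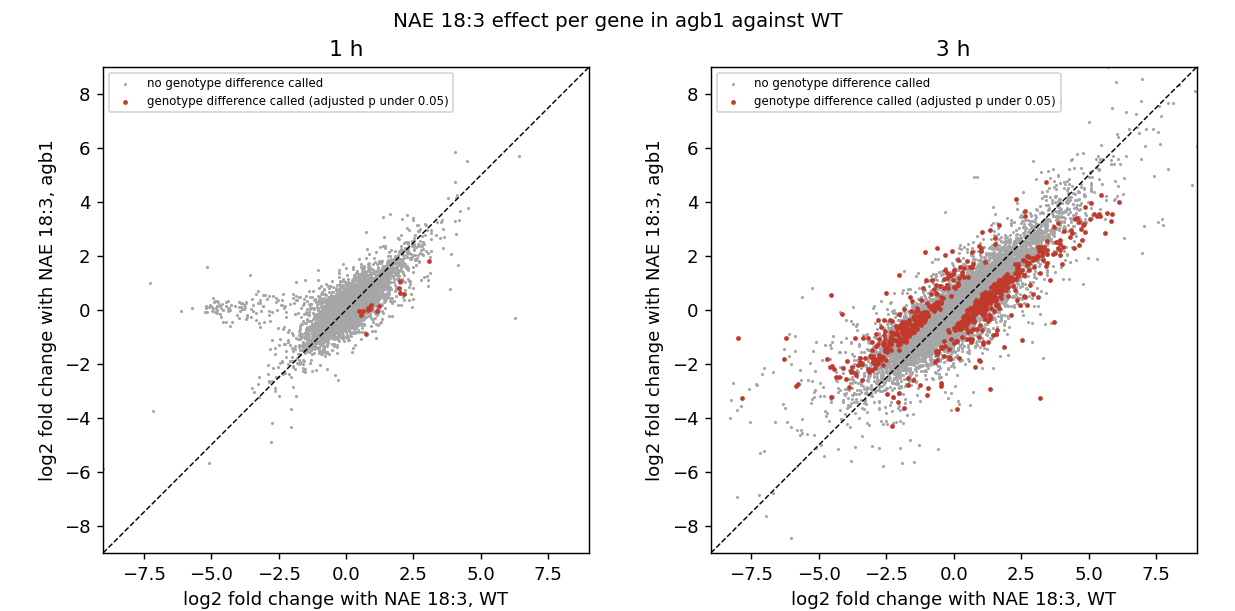
log2 fold change with NAE 18:3 in agb1 (vertical axis) against WT (horizontal axis), 1 point per tested gene, at 1 h (left) and 3 h (right), with values limited to the range shown. Red points are the 16 genes at 1 h and 613 genes at 3 h whose genotype difference was called, and the dashed line marks equal effects.

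Across genes, the NAE effects in the genotypes had a Pearson r of 0.68 (Spearman rho 0.586) over 21255 genes at 1 h and 0.872 (rho 0.853) over 20672 genes at 3 h. Over genes called in WT at the other time point r was 0.82 (rho 0.72, 11940 genes) at 1 h and 0.923 (rho 0.932, 4266 genes) at 3 h. Genes are not independent replicates, so no p is given. The 2615 genes that rose in WT at 1 h had a median of 1.11 in WT and 0.82 in agb1 at 3 h, and 70% of them had the smaller value in agb1. By fry the difference between genotypes had an adjusted p of 0.658 over 16 tests, both for these and for the 1651 genes that fell in WT at 1 h (medians -0.80 and -0.71). For the genes chosen at 3 h and tested at 1 h the adjusted p was 0.881 for rises and for falls.

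The NAE effect at 3 h differed between the genotypes for 613 genes, and the heat shock list stood out among the lists. Of 22 heat shock genes 14 were called with a smaller effect in agb1 (16 adjusted over the list alone), with a median difference of -1.71 (adjusted p = 1.22e-47, and adjusted p = 0.015 with an estimated correlation). HSP17.6B differed by -2.31 (SE 0.17), HSP17.6A (AT5G12030) by -2.54 (SE 0.42), HSP23.5 by -1.70 (SE 0.13) and the related gene AT1G07400 by -2.74 (SE 0.28). HSP17.6B started at 78.7 ± 7.48 CPM in agb1 against 23.3 ± 1.48 in WT, and reached 930 ± 66.9 CPM against 1360 ± 172 (SD, n = 3). The antenna list had 7 of 19 genes called with a higher value in agb1 (10 adjusted over the list alone) and a median difference of 0.52 (adjusted p = 8.13e-14, and adjusted p = 0.32 with an estimated correlation). LHCB2.3 (AT3G27690) differed by 2.45 (SE 0.29) and LHCB2.1 by 1.44 (SE 0.20). LHCB2.1 fell from 282 to 65.3 CPM in WT, and in agb1 from 136 ± 2.18 to 85.3 ± 17 CPM.

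Beyond these lists, the largest differences toward agb1 were AT1G60590 (4.57, SE 1.04), AT3G28220 (2.91, SE 0.44), AT2G10940 (2.89, SE 0.38), the pectate lyase gene AT1G67750 (2.62, SE 0.40) and CYP710A2 (AT2G34490, 2.47, SE 0.50). Toward WT they included the methyltransferase gene AT5G04380 (-3.65, SE 0.40), the elicitor peptide gene PROPEP3 (AT5G64905, -2.55, SE 0.53) and AT5G62280 (-2.34, SE 0.29). NDL3 (AT2G19620), BAM5 and TPS8 differed by 1.17 (SE 0.20), 1.4 (SE 0.26) and -1.32 (SE 0.30). Other lists shifted by less: chlorophyll by 0.31 with 2 of 23 genes called (adjusted p = 5.37e-05, and adjusted p = 0.518 with an estimated correlation), photosystem by 0.25 (adjusted p = 0.00054, and adjusted p = 0.706 with an estimated correlation) and greening by 0.16 (adjusted p = 0.00321, and adjusted p = 0.598 with an estimated correlation). Cell cycle genes differed by 0.62 (adjusted p = 2.3e-05, and adjusted p = 0.575 with an estimated correlation), detoxification by -0.53 (adjusted p = 0.0174, and adjusted p = 0.861 with an estimated correlation), auxin by -0.54 (adjusted p = 0.0157, and adjusted p = 0.511 with an estimated correlation) and endoplasmic reticulum stress by -0.53 (adjusted p = 2.11e-05, and adjusted p = 0.368 with an estimated correlation). The auxin call was lost without WT DMSO replicate 3, WT NAE replicate 3 or agb1 NAE replicate 3. The detoxification call was lost without agb1 DMSO replicate 3. Of 2441 loci with a chloroplast location 40 had a higher and 23 a lower effect in agb1 (median 0.05, adjusted p = 0.0803).

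Of the 613 genes, 305 rose in WT, 285 of them with a lower value in agb1, and 245 fell in WT, 224 of them with a higher value in agb1. Of the same 613, 349 also differed between the genotypes under DMSO and 380 under NAE 18:3. Under NAE 18:3 and not under DMSO 262 differed, and under DMSO and not under NAE 18:3 231 did. Of the 349, 324 differed under DMSO in the opposite direction to the difference in effect, a sign that the subtraction itself favours. Among the 2971 genes that rose at least 2-fold in WT, 231 had a called difference, 219 of these had a lower value in agb1, and 41 were not called there. Among the 2823 that fell at least 2-fold, 207 had one, 197 of these had a smaller change in agb1, and 35 were not called there. The difference contains the WT change by which these genes were grouped, so the subtraction also favours a smaller change in agb1 here. These counts by WT direction are thus no independent evidence of a weaker response. The fry tests on genes chosen at the other time point did not pass. The count of 613 was 198 without WT DMSO replicate 2, 396 and 335 without WT NAE replicates 1 and 2, 1394 without agb1 DMSO replicate 2, and 189 and 199 without agb1 NAE replicates 1 and 2. DESeq2 called 1377. The call of AT1G60590 was lost in 8 alternatives, that of PROPEP3 in 5, CYP710A2 in 3 and TPS8 in 10.

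**Figure D3:**
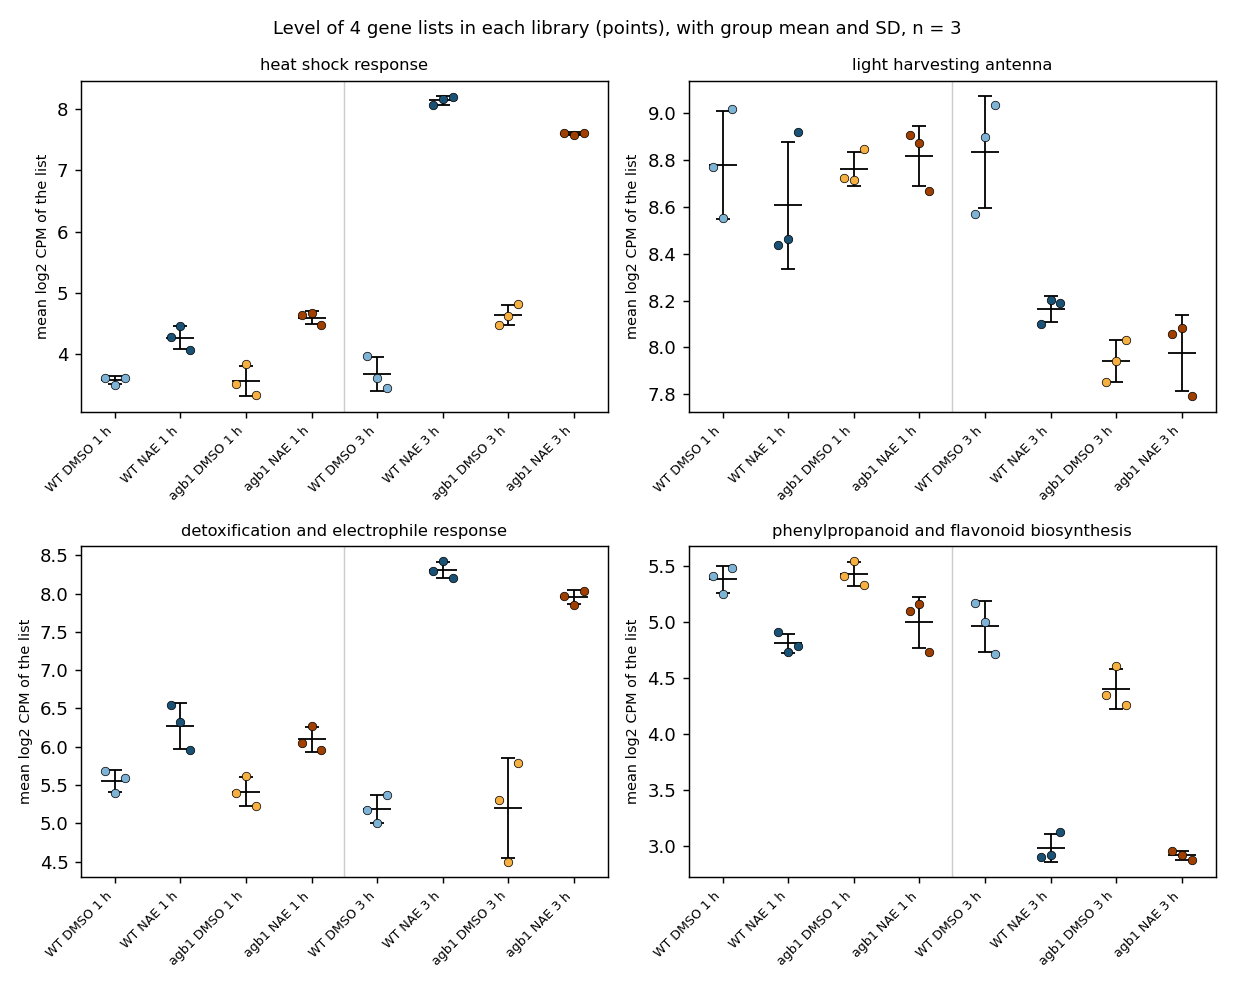
Mean log2 CPM of 4 gene lists in each library (points), with group mean and SD (bars, n = 3), for the 8 groups at 1 h and 3 h. The vertical axes differ between panels and do not start at 0; heat shock genes under DMSO at 3 h lie higher in agb1 than in WT, and antenna genes lower.

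Under DMSO at 3 h, agb1 seedlings had lower levels than WT of photosynthesis and jasmonate genes and higher levels of heat shock genes. All 19 antenna genes were lower, with a median of -0.79 (adjusted p = 3.26e-18, and adjusted p = 0.259 with an estimated correlation), LHCB2.3 by -1.79 (SE 0.20) and LHCB3 (AT5G54270) from 762 ± 82.9 in WT to 344 ± 46.7 CPM in agb1 (SD, n = 3). Of 30 photosystem genes 25 were lower (27 adjusted over the list alone, median -0.66, adjusted p = 3.36e-16, and adjusted p = 0.263 with an estimated correlation), with PSAH2 at -0.81 (SE 0.09) and PSBTN (AT3G21055) at -0.92 (SE 0.13). Of 20 Calvin cycle genes 18 were lower (20 adjusted over the list alone, median -0.74, adjusted p = 2.38e-17, and adjusted p = 0.218 with an estimated correlation), with CP12-2 at -1.49 (SE 0.16) and FBA1 at -1.41 (SE 0.15). Of 23 chlorophyll genes 12 were lower (14 adjusted over the list alone, adjusted p = 4.39e-06, and adjusted p = 0.419 with an estimated correlation), HEMA1 (AT1G58290) by -0.67 (SE 0.10), and of 24 greening genes 7 (adjusted p = 0.000637, and adjusted p = 0.518 with an estimated correlation), GLK1 by -1.84 (SE 0.10) and GNC (AT5G56860) by -1.35 (SE 0.17). Of 27 jasmonate genes 15 were lower (16 adjusted over the list alone, median -0.73, adjusted p = 4.64e-11, and adjusted p = 0.107 with an estimated correlation), LOX2 (AT3G45140) by -3.75 (SE 0.29) and AOS (AT5G42650) by -1.15 (SE 0.11). Of 22 heat shock genes 14 were higher (16 adjusted over the list alone, median 1.09, adjusted p = 1.84e-19), HSP17.6B by 1.76 (SE 0.12) and HSP23.5 by 1.22 (SE 0.10).

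The largest single differences under DMSO at 3 h included FSD1, at 4.68 ± 0.184 CPM in WT and 379 ± 40.6 CPM in agb1 (SD, n = 3, log2 difference 6.34, SE 0.31). MRN1 (3.2, SE 0.50), AT1G74870 (2.97, SE 0.42), AT5G15120 (2.65, SE 0.32) and the desaturase gene AT3G02620 (2.60, SE 0.31) were also higher in agb1. Lower were AT5G23700 (-5.34, SE 0.27), AT5G44440 (-5.03, SE 0.31), the succinate dehydrogenase gene SDH1-2 (AT2G18450, -4.41, SE 0.16), the meiotic gene SHOC1 (AT5G52290, -4.24, SE 0.19) and LOX2. In the lipid metabolism list 6 of 18 were lower and 1 higher (adjusted p = 0.000127, and adjusted p = 0.263 with an estimated correlation), HPL1 (AT4G15440) by -4.73 (SE 0.27) and FAD8 (AT5G05580) by -1.4 (SE 0.11). Of 28 defence genes 9 were lower and 1 higher (adjusted p = 0.0113, and adjusted p = 0.545 with an estimated correlation), WRKY53 (AT4G23810) by -1.42 and WRKY22 by 1.73 (SE 0.16 and 0.19). In the endoplasmic reticulum stress list 3 of 12 were higher (adjusted p = 0.00321, and adjusted p = 0.545 with an estimated correlation), TIN1 by 1.62 and NAC103 (AT5G64060) by 1.2, and in the cell cycle list 5 of 24 were lower and 1 higher (adjusted p = 0.0295, and adjusted p = 0.854 with an estimated correlation), CDKB1;2 (AT2G38620) by -1.22 and AUR1 (AT4G32830) by -1.01. CSD2 (AT2G28190), BAM5, MYB75 (AT1G56650), MYB12 (AT2G47460), FKF1 (AT1G68050) and KIN2 (AT5G15970) were lower by -1.25, -3.23, -2.39, -0.94, -0.64 and -0.92, and TPS10 (AT1G60140) was higher by 0.91. Of 2441 loci with a chloroplast location 163 were higher and 467 lower (adjusted p = 0.0312, and adjusted p = 0.518 with an estimated correlation). In all 1621 genes were higher and 2300 lower in agb1, and the count of 3921 was 2503 without WT DMSO replicate 2. The 1621 higher genes were 940, 709 and 1062 without WT DMSO replicates 1, 2 and 3, and 856 without agb1 DMSO replicate 3. AT5G23700 and SHOC1 overlap neighbours on the opposite strand, so their reads could belong to either.

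The genotype difference under DMSO was little alike at the 2 time points. Across 20365 genes it had a Pearson r of 0.126 (Spearman rho 0.066). At both times 651 genes were called, 485 in the same and 166 in opposite directions. Lower at both were 317 genes, where independent lists would share 134, and higher at both 168, where they would share 92. FSD1 was called in opposite directions, at -1.70 at 1 h and 6.34 at 3 h. With 12 libraries at each time, the change of the genotype difference between times was called for 3528 of 21700 genes.

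The NAE effect changed between 1 h and 3 h for 10422 of 21700 genes in WT, 5474 toward a higher and 4948 toward a lower value at 3 h. The largest changes were in 18S ribosomal RNA (AT3G41768, 7.30, SE 1.70), the plastid locus ATCG00020 (6.42, SE 1.65), AT2G23110 (6.29, SE 0.70), AT1G60590 (-8.86, SE 0.80), AT5G20790 (-6.18, SE 0.55) and the galactolipid synthase gene MGDC (AT2G11810, -5.90, SE 0.80). The ribosomal and plastid values rest on WT DMSO replicate 2 at 1 h, which held 5.288% ribosomal counts against at most 0.076% in the other 11 libraries of that time. In agb1 7489 genes changed, 3682 upward and 3807 downward, with AT3G43250 (5.95, SE 0.62), AT4G37710 (5.76, SE 0.43) and AT3G28600 (5.63, SE 0.78) at one end. BGLU34 (-5.80, SE 1.12), EXPA11 (-5.27, SE 0.41) and BGLU35 (-4.88, SE 1.02) stood at the other. Of 3177 genes called in WT at both times 2885 (90.8%) kept their direction, and of 2235 in agb1, 2130 (95.3%).

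Organelle transcripts are only partly retained by poly(A) selection, so their share depends on the library. With NAE 18:3 in WT at 1 h the 85 plastid loci had a median of -3.65 (adjusted p = 6.12e-07, and adjusted p = 0.818 with an estimated correlation) and the 19 mitochondrial loci one of -3.90 (adjusted p = 0.0113, and adjusted p = 0.861 with an estimated correlation). The medians were -0.42 and -0.30 without WT DMSO replicate 2. Without that library, and with the preset correlation, the plastid list still passed its test and the mitochondrial list did not. The differences in effect at 1 h were 3.69 for plastid loci (adjusted p = 2.25e-23, and adjusted p = 0.518 with an estimated correlation) and 4.14 for mitochondrial loci (adjusted p = 1.02e-07, and adjusted p = 0.555 with an estimated correlation), and again only the plastid call stood without it. Since the WT medians were -0.42 and -0.30 without that library, most of the size of both differences rests on it. At 3 h in agb1, 51 of 85 plastid loci rose (median 1.01, adjusted p = 0.000422, and adjusted p = 0.814 with an estimated correlation) and 17 of 25 mitochondrial loci (median 1.23, adjusted p = 0.0108, and adjusted p = 0.706 with an estimated correlation). In WT at 3 h 16 of 85 plastid loci (adjusted p = 0.171) and 9 of 25 mitochondrial loci (adjusted p = 0.269) rose, among them ATMG00660 by 1.41 (SE 0.29), and the plastid difference between genotypes was 0.40 (adjusted p = 0.00321, and adjusted p = 0.864 with an estimated correlation). The call of that plastid difference was lost without WT DMSO replicate 3, WT NAE replicate 3 or agb1 DMSO replicate 3. The mitochondrial call in agb1 at 3 h was lost without agb1 DMSO replicate 3. Organelle loci took 0.184% of counts in agb1 under NAE 18:3 at 3 h and 0.094% under DMSO (two-sided exact permutation p = 0.1, the smallest that 3 against 3 libraries allow). Ribosomal RNA, also without a poly(A) tail, took 0.188%, 0.257% and 0.126% of counts in these NAE libraries and 0.086%, 0.061% and 0.039% under DMSO.

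**Figure D4:**
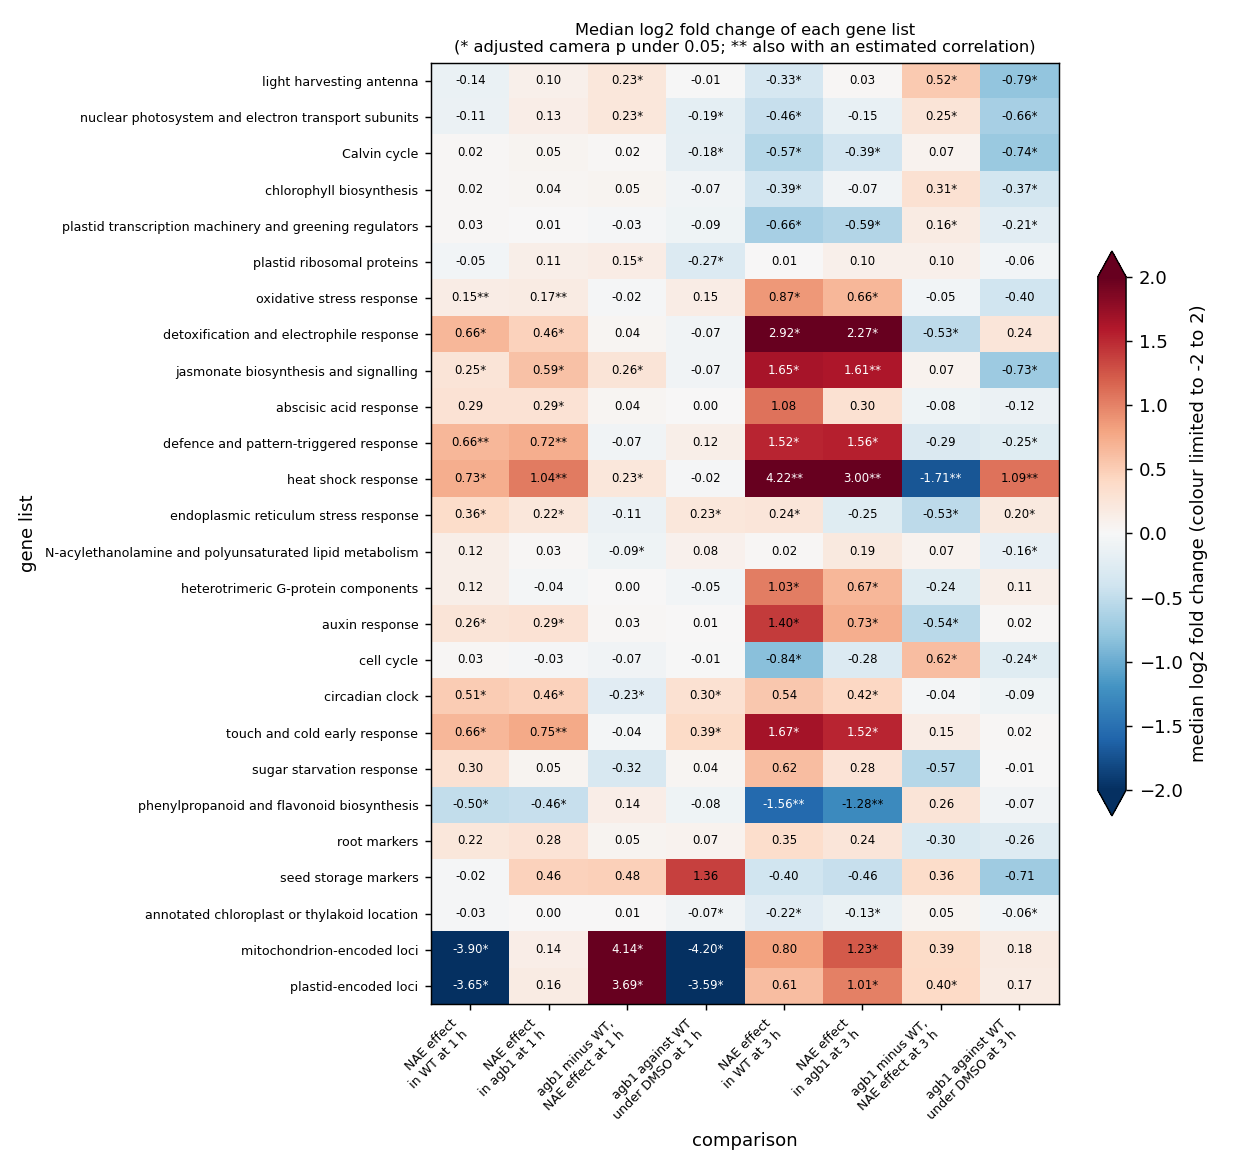
Median log2 fold change of each of the 26 gene lists (vertical axis) in the 8 within-time comparisons (horizontal axis), in colour and as numbers. One star marks a camera adjusted p under 0.05 and a pair of stars marks that it also held with an estimated correlation, as for heat shock genes in 5 of the 8 comparisons.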

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

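The results here are differences between the genotypes or the time points that passed a test of the difference itself; the last paragraph gives splits of the libraries for the other comparisons. The tests that compared agb1 with WT under NAE 18:3 and those at equal depth were chosen only after the result was seen. Single outlying samples were not tested within the groups of 3 libraries.

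The heat shock list rose less with NAE 18:3 in agb1 than in WT at 3 h, with a median difference of -1.71 (SE 0.14 over libraries left out in turn). With libraries thinned to equal depth the median was -1.71, but thinning keeps expected fold changes, so this cannot decide on depth. With the trend on transcript length and GC content removed it was also -1.71. That trend had an SD of 0.061 over genes, too small to account for the difference. Heat shock genes were higher in agb1 under DMSO at 3 h (median 1.09) but not at 1 h (median -0.02). At 3 h under NAE 18:3, 10 of 22 were called lower than in WT and 0 higher (median -0.50, SE 0.08). The list passed there with the preset correlation (camera adjusted p = 5.52e-05) and missed with an estimated one (adjusted p = 0.733). A difference under DMSO alone is thus not the whole cause for the 10 called genes, but the test does not settle this for the list. A weaker response of agb1 to the lipid on top of a raised DMSO level may explain both medians at 3 h, as a hypothesis found and tested on the same data. At 1 h no weaker response was seen. Under NAE 18:3 the list median against WT was then 0.19 (camera adjusted p = 0.016, and adjusted p = 0.794 with an estimated correlation). A difference in seed stock or handling between the genotypes stays open.

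The antenna list had a median difference of 0.52 at 3 h (SE 0.20 over libraries left out in turn), and its call was lost with an estimated correlation (adjusted p = 0.32). The median difference was 0.51 at equal depth, but thinning keeps expected fold changes, so this cannot decide on depth. With the trend on length and GC content removed it was 0.49. That trend, with an SD of 0.061 over genes, thus accounts for little of the difference. All 19 genes were lower in agb1 under DMSO, and under NAE 18:3 the list median against WT was -0.25 (SE 0.08, adjusted p = 0.225), with 2 genes called higher and 4 lower. Because members went both ways, this median does not decide whether the difference lies under DMSO alone, and that stays open beside a different response to the lipid.

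At 1 h 16 genes and 9 lists differed in NAE effect between the genotypes, but each of the 9 lists missed 0.05 with an estimated correlation (adjusted p 0.518 to 0.782). Of 100 splits of the libraries 4 gave at least 16 genes, a share under 0.05, but the highest other split gave 55. At 3 h 613 genes and 10 lists differed, and of the 10 the heat shock list alone passed with an estimated correlation. Of 100 splits 2 gave at least 613, and the highest other gave 2057. The effect differed between 3 h and 1 h for 10422 genes in WT and 7489 in agb1; 3 of 100 splits gave as many in each, a share under 0.05, with 11681 and 11032 as the highest others. In each case the highest other split exchanged the labels of 2 DMSO libraries of each side and of no NAE library. Such a split turns a difference between the DMSO groups into a difference in effect, so its high count points to that structure of the samples, and the shares are no test against samples without any difference.

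The single genes with the largest tested differences at 1 h were AT1G19200 (-1.63), AT4G32480 (-1.56), AT2G20670 (-1.25), AT3G03790 (-1.19) and AT5G19120 (-1.13) among those named by rule. At 3 h they were AT1G60590 (4.57), AT3G28220 (2.91), AT2G10940 (2.89), AT1G67750 (2.62) and CYP710A2 (2.47) toward agb1. Toward WT they were AT5G04380 (-3.65), AT1G07400 (-2.74), PROPEP3 (-2.55), HSP17.6A (-2.54) and AT5G62280 (-2.34).

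For comparisons of 3 with 3 libraries, 1 of the 10 splits, the real one, gave as many genes each time, and 10 splits are too few for a share under 0.05. The real count and the highest other were 4348 and 1 for NAE 18:3 in WT at 1 h, 2935 and 0 in agb1 at 1 h, and 2419 and 0 for agb1 against WT under DMSO at 1 h. At 3 h they were 12094 and 0 in WT, 10442 and 0 in agb1, and 3921 and 220 for the genotypes under DMSO.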

How the results depend on the processing

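Thinning to equal depth was the alternative chosen only after the data were seen. With a 2-fold minimum the counts were, for NAE 18:3, 970 in WT and 825 in agb1 at 1 h, and 5794 and 4348 at 3 h. They were 7 and 340 for the genotype difference in NAE effect at 1 h and 3 h, 301 and 1029 for the genotypes under DMSO, and 4789 and 3031 for the time difference in WT and agb1. A stricter minimum passes fewer genes by construction. The genotype difference at 1 h gave 78 genes with DESeq2 and 5 at equal depth, and at 3 h DESeq2 gave 1377; DESeq2 shared 16 of 16 and 611 of 613 genes with edgeR. With only the 6 libraries compared, 2466 genes differed between the genotypes under DMSO at 3 h, from fewer samples. With the replicate number as a block, the unadjusted fry value for genes lowered by NAE 18:3 at 3 h was 0.0449, and with a mean of at least 10 CPM the correlation at 3 h was 0.936. With an estimated correlation 13 list tests passed, against 95. The cause was not tested for DESeq2, equal depth, the block or the CPM minimum.

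With each library left out in turn, NAE 18:3 in WT at 1 h gave 2684 (without WT NAE replicate 2) to 4600 genes. The genotype difference at 1 h gave 1 to 32, and at 3 h 189 to 1394. The genotypes under DMSO gave 851 to 2734 genes at 1 h and 2503 to 4374 at 3 h. The report names each library that moves one of these totals by over 1.5 times; the highest values of 4600 and 2734 came without agb1 NAE replicate 3, and 4374 without WT NAE replicate 3. The unadjusted fry value at 3 h, 0.0834 for genes raised and 0.123 for genes lowered, ran from 0.0431 (without agb1 DMSO replicate 2) to 0.545 and from 0.00481 (without agb1 DMSO replicate 2) to 0.217. For genes lowered it was also 0.0321, 0.0324 and 0.0227 without WT DMSO replicates 1, 2 and 3, and 0.0183 and 0.0173 without agb1 DMSO replicates 1 and 3. The correlation at 3 h ran from 0.822 (without WT NAE replicate 1) to 0.877.

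Other ranges of totals stayed within 1.5 times: 2287 to 3045 for agb1 at 1 h, 10840 to 12293 and 8766 to 10960 for WT and agb1 at 3 h, 9346 to 10377 and 6493 to 8026 for the time differences, and 92 to 104 list tests. Of the named-gene repeats 6670 stayed on their side of the threshold, 8 passed it and 150 missed it; of the list repeats 2890 stayed, 89 passed and 125 missed. No called result reversed direction. The median genotype difference in NAE effect over all genes at 3 h, -0.023, was 0.032 and 0.028 without WT DMSO replicates 1 and 2, 0.038, 0.034 and 0.053 without agb1 DMSO replicates 1, 2 and 3, and 0.003 with DESeq2. The fry direction, which did not pass with all libraries, did change: for genes raised, at 1 h without WT NAE replicate 1 or 2, agb1 DMSO replicate 2 or agb1 NAE replicate 1; for genes lowered, at both times with a 2-fold minimum and at 1 h without WT DMSO replicate 2, WT NAE replicate 3, agb1 DMSO replicate 3 or agb1 NAE replicate 3. Equal depth left 5 of 16 genotype differences in NAE effect at 1 h and gave 613 at 3 h, 533 of them shared with the main 613. Leaving out any of 11 libraries in turn also left 1 to 4 of the 16, so the fall does not single out depth. In simulation 28.4% of 1.5-fold differences were recovered at 1 h and 1.5% at 3 h, with median SEs of 0.15 and 0.231; depth was not varied there.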

Other observations

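The tests on the 10 genes and on organelle loci were chosen only after the result was seen, as were the phosphate and copper lists and the comparison of the genotypes under NAE 18:3. Phosphate starvation genes rose with NAE 18:3 in WT at 1 h, 11 of 16 with a median of 1.25 (adjusted p = 9.67e-13, and adjusted p = 0.066 with an estimated correlation). At 3 h 2 rose and 9 fell in WT (median -0.76, adjusted p = 0.163) and 2 rose and 7 fell in agb1 (median -0.41, adjusted p = 0.179), with a list difference of 0.10 (adjusted p = 0.559). In agb1 at 1 h 4 of 16 rose, with a median of 0.37 and an adjusted p of 0.0356 (adjusted p = 0.574 with an estimated correlation), so the response may be shared in part. The list difference at 1 h was -1.02 (adjusted p = 4.01e-20, and 0.035 with an estimated correlation), while the smallest adjusted p of a single member was 0.063, for SRG3 (AT3G02040). The list was chosen because its genes rose in WT, so neither its rise there nor the difference, which contains that rise, is independent evidence. Under DMSO 5 of 16 were lower in agb1 at 1 h (median -0.35, adjusted p = 8.39e-05, and adjusted p = 0.341 with an estimated correlation) and 13 of 16 at 3 h (median -1.47, adjusted p = 3.31e-17).

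Copper deficiency genes lay lower in agb1 than in WT under DMSO at 1 h (3 of 6, median -0.44, adjusted p = 2.74e-05) and higher at 3 h (4 of 6, median 0.83, adjusted p = 1.04e-06). Without FSD1 the median at 3 h was 0.80 (3 of 5 higher, adjusted p = 0.0284, and adjusted p = 0.104 with an estimated correlation), so that gene alone does not carry the list at 3 h, and at 1 h it was -0.35 (2 of 5 lower, adjusted p = 0.00174, and adjusted p = 0.0522 with an estimated correlation). Of the 9 list entries 6 were tested. At 3 h COPT1 (AT5G59030, -0.08) and COPT6 (AT2G26975, -0.50) did not follow the list and were not called. The list was chosen after these data were seen, so its tests are not independent evidence. CSD2, which falls when copper is short, was at 1320 CPM in WT and 558 CPM in agb1 under DMSO at 3 h, but at 1 h it was at 851 and 890 CPM and did not follow the list. A difference in copper supply between these samples may be a candidate explanation, and it was not measured.

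At 3 h 10 genes set the 6 WT libraries at least 4-fold apart from the other 18, 9 higher and 1 lower. SDH1-2 was at 85.7 CPM in them and 4.15 CPM in WT at 1 h, SHOC1 at 14.5 and 0.798, SPO11-2 (AT1G63990) at 3.81 and 0.263, and FSD1 at 5.5 and 223. The median size of the log2 difference between WT and agb1 was 0.53 at 1 h and 4.12 at 3 h, and between the times in agb1 it was 0.86. The choice of genes that set these libraries apart largely fixes these sizes, so they decide nothing about genotype alone or the later time alone. The size was 3.71 between WT under DMSO at 3 h and WT at 1 h and 3.88 with NAE 18:3, so a separate seed stock or growth batch of the WT seedlings at 3 h cannot be told apart from an effect of genotype and time together, because the design holds 1 WT set per time. Comparisons between WT and agb1 at 3 h, and of the genotype difference between the times, could carry such a difference. In the time difference of the NAE effect in WT a constant shift cancels, but a batch that alters the response to NAE 18:3 would not.

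Plastid and mitochondrial loci had medians of -0.42 and -0.30 with NAE 18:3 in WT at 1 h when WT DMSO replicate 2 was left out, against -3.65 and -3.90 with it. More RNA without a poly(A) tail in that library is a candidate explanation for most of the size, but the plastid list still passed its test without it. Under DMSO at 1 h, with the trend on exon length and GC content removed, the median of agb1 against WT was -0.09 for photosystem genes and -0.17 for plastid ribosomal genes (SE 0.13 each over libraries left out in turn), against -0.19 and -0.27 before. Transcript length or GC content could thus account for part of these shifts, and the spread is too wide to settle it.

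Under NAE 18:3 1907 genes differed between the genotypes at 1 h and 4743 at 3 h. Of these, 942 and 1912 also differed under DMSO, 940 and 1829 in the same direction. In all 12 agb1 libraries 3 genes were higher and 8 lower than in all 12 WT libraries, among 25376 genes. They include AT1G27565 (3.61 and 0.00378 CPM in agb1 and WT), HEI10 (AT1G53490, 3.01 and 12.3) and PUB26 (AT1G49780, 8.93 and 14.6), chosen after their values were seen.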
